A study of Homo sapiens with 29 samples.

How the data were processed

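The series holds 29 Affymetrix Gene 1.0 ST arrays of human CD4+ T cells from peripheral blood. Cells were isolated by negative selection and left unstimulated or activated with beads carrying antibodies to CD3 and CD28, alone, with IFN-beta or with a Th17 cocktail. The groups were unstimulated (4 arrays, at 0, 4, 24 and 72 h), activated, IFN-beta and Th17 (7 arrays each, at 45 min and 2, 4, 10, 24, 48 and 72 h), and IFN-beta at 1 U/ml and at 1000 U/ml (2 arrays each, at 45 min and 10 h). Groups and times were taken from the labels. The protocol lists several IFN-beta doses, and the labels of the 7 IFN-beta arrays do not say which was used. The number of donors, and whether cells were pooled, is not stated. The title calls the cells fresh and the protocol calls them frozen and thawed, and 1 label of the unstimulated 4 h array says 0 h; the title was followed.

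The deposited values are normalized signal intensities, made with RMA per the submitters' processing notes, which give no version. The plan assumed log2 values. The deposited intensities are linear, so log2 was taken here before any test. Median intensity was 88.9 to 99.6 per array, and no further normalization was applied in the reported values. Of the 21916 probe sets, 18965 map to 1 gene symbol in the probe table, 1528 to several and 1423 to none. Only those with 1 symbol were tested. For the 554 genes with more than 1 probe set the one with the highest mean was used, which left 18260 genes, all of which were tested without a filter on level. In the 0 h column 50.2% of the values carry 5 decimals, where the other columns have at most 4. Whether that column is a mean of 2 arrays is not stated, and it was counted as 1 array.

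Genes were tested with limma 3.58.1 in R 4.3.3 (moderated t or F tests, two-sided, Benjamini-Hochberg adjusted p under 0.05). Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. There were no replicates: 1 array per group and time. The time points served as repeats and entered the models as a block, additive with group. Activated was set against unstimulated at 4, 24 and 72 h in a fit of 12 arrays. The comparisons of IFN-beta, Th17 and activated cells, the change over time and the early against late interaction used 21 arrays, with the early phase up to 4 h. The doses, and each time against the 4 unstimulated arrays, used 25 arrays. The comparisons at single times share their controls, so overlaps between them are not given.

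Lists of genes, 33 in number, were written before the data were examined. They cover interferon responses, T cell activation and subsets, growth, metabolism, stress and markers of other blood cells. Lists were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry; p was adjusted over the 33 lists. "Adjusted over the list alone" means a Benjamini-Hochberg correction over the genes of that list. Pairs of arrays of the same time gave the number of times with the same direction.

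Named genes followed a rule also written before the data were examined. It takes the 10 largest rises and falls past the threshold with the same sign in all but at most 1 pair, 5 of each at single times, the 10 largest ranges over time, up to 4 genes per list and 10 interferon-stimulated genes for the doses. X-inactivation and Y-linked genes, receptor segments, small RNAs and unnamed loci are left out. Genes outside the rule are marked where they appear.

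The gene tests of some comparisons were tried on simulated data with 200 changed genes among 18260. Each simulated change was the same on all arrays of the shifted group, and the noise was independent between arrays. For activated against unstimulated, 68.7% of genes with a true log2 difference of 1 were recovered, 95.5% at 2 and 100% at 3, with 11 unchanged genes called. For IFN-beta against activated the shares were 79.1%, 95.5% and 100%, with 14 unchanged genes called, and for 24 h against unstimulated 61.2%, 97.0% and 98.5%, with 11. In the data the IFN-beta and Th17 differences varied with time and some arrays stood apart. The shares therefore do not tell how many such changes could be found, and a lack of called genes is not a lack of change.

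Alternatives planned before the data were examined were the mean of a gene's probe sets, only genes above the median level, a floor at the 20th percentile, cyclic loess, centring on the housekeeping list, a variance prior with trend, array weights, no time block, only the 2 groups compared, another baseline, the activated arrays alone, the dose arrays counted as IFN-beta and leaving out each time in turn. Quantile normalization, leaving out the IFN-beta and Th17 arrays at 48 h, and leaving out all arrays at 45 min and 48 h were added after the data were seen. Groups were also split in other ways to count how often as many genes were called. Raw array files, sex, age and other donor traits were not analysed here.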

Results

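The series followed human CD4+ T cells, taken from peripheral blood by negative selection, through 72 h of culture. Messenger RNA was measured on 29 single-colour Affymetrix gene arrays. In 7 arrays the cells were activated with beads that carry antibodies to CD3 and CD28, the T cell receptor complex and its main costimulatory receptor. A further 7 arrays held cells activated together with interferon beta (IFN-beta), a type I interferon, at a dose that the labels do not give, and 7 held cells activated in a Th17 cocktail of IL6, IL23, IL1-beta, TGF-beta and antibodies that block interferon gamma and IL4. These 21 arrays cover 45 min and 2, 4, 10, 24, 48 and 72 h, with 1 array for each group and time. Unstimulated cells were measured on 4 arrays, at 0, 4, 24 and 72 h. The other 4 arrays held activated cells with 1 U/ml or 1000 U/ml of IFN-beta, at 45 min and at 10 h. No group had a second array at the same time, so time points served as the repeats. The number of donors is not stated in the labels, and the results describe these cultures.

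Median intensity lay between 88.9 and 99.6 on the 29 arrays. The number of arrays is among the limits to the precision. The IFN-beta and the Th17 array at 48 h stood apart: their median Spearman correlation with the other arrays, across genes, was 0.866 and 0.457, and the interquartile range of their log2 values was 1.75 and 1.53. In the other Th17 arrays the median correlation was between 0.911 and 0.956. To a lesser degree the array labelled activated 45 min differed from the other arrays of its time. Its highest correlation with another array was 0.979, with IFN-beta at 2 h, where those arrays had 0.990 to 0.993. At 45 min, interferon-stimulated genes were lower on the array labelled IFN-beta than on the array labelled activated. Every IFN-beta direction that uses these arrays therefore rests on their labels. The array labelled activated is also the control of the Th17 cocktail at 45 min and enters the change over time.

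**Figure D1:**
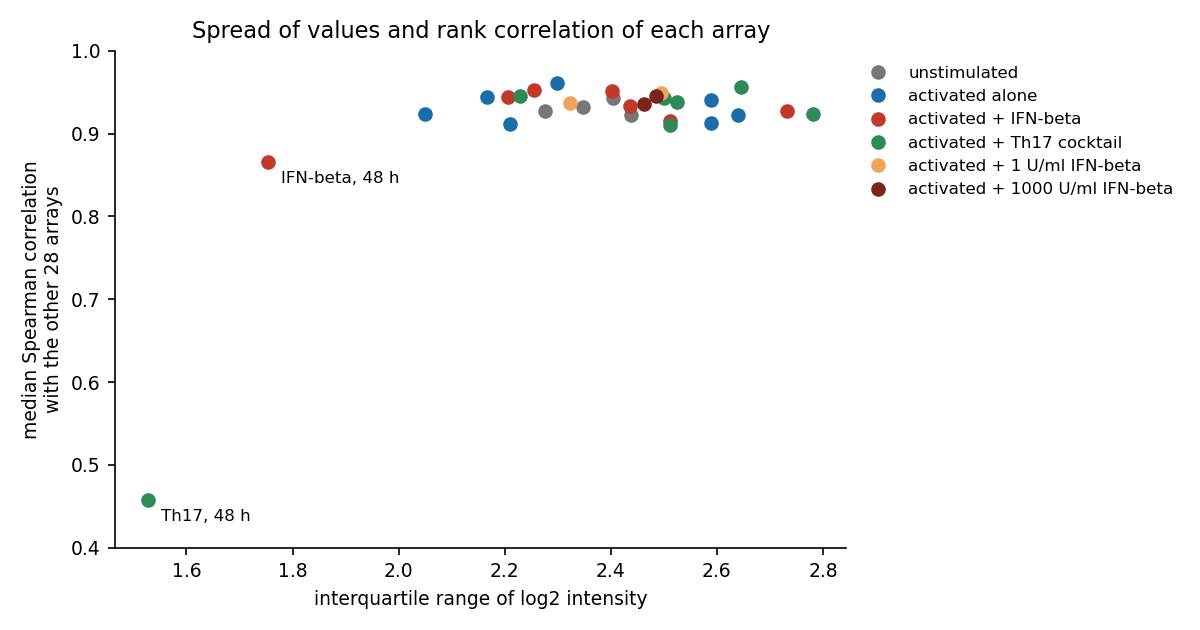
The median Spearman correlation of each array with the other 28 arrays is plotted against the interquartile range of its log2 intensities; each point is 1 array, coloured by group. The Th17 array at 48 h lies at 0.457 and the IFN-beta array at 48 h at 0.866.

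The first comparison asked what activation alone did to the cells, matching culture time: activated against unstimulated arrays at 4, 24 and 72 h. Cytokine genes showed the largest rises. IL2, the growth factor of activated T cells (probe set 8102697; GRCh38.p14 chromosome 4, 122451470 to 122456725), rose by 5.66 on the log2 scale (SE 0.756, adjusted p = 0.00142). The chemokine gene CCL4 rose by 4.98 (SE 0.477, adjusted p = 0.000421), IFNG by 4.93 (SE 0.930, adjusted p = 0.00616), IL21 by 4.75 (SE 0.215, adjusted p = 1.33e-05) and IL3 by 4.68 (SE 0.735, adjusted p = 0.00274). TNFRSF9, SLC27A2, CD200, IRF8 and CD109 rose by 4.15, 4.11, 4.04, 4.00 and 3.98. The largest falls were in VSIG1, which fell by 3.49 (SE 0.407, adjusted p = 0.000863), and TCP11L2, which fell by 3.45 (SE 0.640, adjusted p = 0.00567). GZMK fell by 2.99, PIK3IP1, an inhibitor of PI3 kinase, by 2.92, the DNA damage kinase gene ATM by 2.79, RIPOR2 by 2.72, GIMAP7 by 2.71, B3GALT2 by 2.64, SESN3 by 2.63 and PDE3B by 2.57. Each of these 20 genes moved in the same direction at all 3 times.

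In all, 3382 of 18260 genes changed (limma, adjusted p under 0.05), 1704 up and 1678 down, of which 900 and 564 by at least 2-fold. Centring on the housekeeping list moved the balance, with 611 up and 13100 down (13711 in all), and with no time block 1309 genes changed. The count was 314 without the 24 h arrays, 1179 without 72 h and 5342 without 4 h. Of the 20 genes above, IL2, IFNG, IL3, TNFRSF9, GZMK, ATM, RIPOR2, GIMAP7, B3GALT2, SESN3 and PDE3B no longer passed without 24 h, and TCP11L2, GZMK, ATM, RIPOR2, SESN3 and PDE3B without 72 h. The count was 4 when only the arrays of the 2 groups were fitted (CD109, IL21, PMAIP1 and, named after its values were seen, B3GNT5). Of 33 gene lists 21 shifted by camera with a preset correlation, 20 by fry and 0 by camera with an estimated correlation.

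Surface receptors and cytokines of activated T cells rose as groups. In the T cell activation list 19 of 27 genes rose (23 adjusted over the list alone), among them IL2RA by 3.97, IRF4 by 3.87 and CTLA4 by 2.93. The list median was 1.42 (adjusted p = 6.57e-15; adjusted p = 0.218 with an estimated correlation). In the cytokine list 17 of 26 genes rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 2.21 (adjusted p = 8.55e-11; adjusted p = 0.218 with an estimated correlation). Of the immediate early list, the transcription factors and phosphatases induced first by receptor signals, 15 of 33 genes rose (18 adjusted over the list alone), including IER3 by 3.40, DUSP6 by 3.23, NR4A3 by 3.06 and EGR1 by 2.85. Its median was 0.84 (adjusted p = 1.31e-07; adjusted p = 0.239 with an estimated correlation).

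Genes that serve growth and division also rose. In the ribosome biogenesis list 33 of 35 genes rose (34 adjusted over the list alone), with DDX21 up by 2.5, WDR12 by 2.39 and NOLC1 by 2.17; the median was 1.5 (adjusted p = 6.66e-25; adjusted p = 0.218 with an estimated correlation). Of 38 DNA replication genes 19 rose (31 adjusted over the list alone), including CDC6 by 3.06, and the median was 1.65 (adjusted p = 3e-11; adjusted p = 0.35 with an estimated correlation). Of 38 mitosis genes 9 rose (24 adjusted over the list alone), including CKS2 by 2.76 and CDC20 by 2.45, and the median was 1.86 (adjusted p = 3.85e-10; adjusted p = 0.368 with an estimated correlation). In the amino acid and ATF4 list 14 of 26 genes rose (17 adjusted over the list alone), with the amino acid transporter genes SLC7A5 and SLC1A5 up by 3.44 and 3.28 and the mitochondrial folate enzyme gene MTHFD2 by 3.44. Its median was 0.93 (adjusted p = 4.01e-11; adjusted p = 0.218 with an estimated correlation).

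Metabolic lists moved the same way. Of 20 glycolysis genes 13 rose (15 adjusted over the list alone), with ENO1 up by 2.18, PFKP by 2.08 and HK2 by 1.93, and the median was 1.06 (adjusted p = 5.18e-09; adjusted p = 0.218 with an estimated correlation). Of 21 cholesterol and lipid synthesis genes 12 rose (16 adjusted over the list alone), with SCD up by 3.19 and HMGCS1 by 2.12, and the median was 1.32 (adjusted p = 4.53e-08; adjusted p = 0.239 with an estimated correlation). All 14 tRNA synthetase genes rose when adjusted over the list alone and 11 over all genes, with a median of 1.25 (adjusted p = 2.45e-10; adjusted p = 0.218 with an estimated correlation). Of 14 heat shock genes 9 rose (10 adjusted over the list alone), with HSPD1 up by 2.39, and the median was 1.29 (adjusted p = 1.61e-06; adjusted p = 0.239 with an estimated correlation). Smaller medians were seen in 2 more lists, 0.64 in oxidative phosphorylation (10 of 30 genes rose, 14 adjusted over the list alone; adjusted p = 6.64e-07; adjusted p = 0.368 with an estimated correlation) and 0.53 in the unfolded protein list (8 of 20 rose, 12 adjusted over the list alone; adjusted p = 7.75e-07; adjusted p = 0.218 with an estimated correlation). The housekeeping list had a median of 0.53 itself, with 10 of 24 genes up (11 adjusted over the list alone; adjusted p = 1.76e-06; adjusted p = 0.275 with an estimated correlation), so centring on it moved the median of all genes to -0.72 and turned the medians of the oxidative phosphorylation and unfolded protein lists below 0.

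Genes of resting T cells fell. In the naive and quiescence list 17 of 23 genes fell (20 adjusted over the list alone): KLF3 fell by 2.26, the interleukin 7 receptor gene IL7R by 2.06 and the chemokine receptor gene CXCR4 by 2.06. The median was -0.99 (adjusted p = 1.73e-10; adjusted p = 0.218 with an estimated correlation). Of 17 T cell identity genes 6 fell and 1 rose (the same counts adjusted over the list alone). Among them TRAT1 fell by 1.70 and the CD3 zeta chain gene CD247 by 1.19. The median was -0.41 (adjusted p = 0.00353; adjusted p = 0.239 with an estimated correlation).

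Genes of the helper subsets were among the risers although no subset cytokine had been added. In the Th17 list 10 of 24 genes rose and 3 fell (12 and 4 adjusted over the list alone), and its median was 0.70 (adjusted p = 0.000212; adjusted p = 0.239 with an estimated correlation). IL17A (probe set 8120210; GRCh38.p14 chromosome 6, 52186375 to 52190638) rose by 3.81 (SE 0.260, adjusted p = 0.000125), IL17F by 2.65 (SE 0.232, adjusted p = 0.000318) and IL22 by 3.83 (SE 0.895, adjusted p = 0.0162). In the Th1 list 5 of 12 genes rose (6 adjusted over the list alone), including GZMB by 2.85 and IL12RB2 by 2.69, and the median was 0.48 (adjusted p = 0.0106; adjusted p = 0.275 with an estimated correlation). In the Th2 list 3 of 12 rose by either adjustment, over all genes or adjusted over the list alone: IL13 by 2.94, IL10 by 2.84 and IL5 by 2.18. Its median was 0.54 (adjusted p = 0.00279; adjusted p = 0.239 with an estimated correlation). In the regulatory T cell list 5 of 12 rose (7 adjusted over the list alone), and the median was 0.75 (adjusted p = 0.000159; adjusted p = 0.224 with an estimated correlation). FOXP3, its defining transcription factor, had a log2 difference of 0.74 (adjusted p = 0.0909). In the IL6 and STAT3 list 9 of 18 rose and 1 fell (10 and 1 adjusted over the list alone), with CISH up by 1.92 and SOCS3 by 1.62, and the median was 0.66 (adjusted p = 0.000351; adjusted p = 0.218 with an estimated correlation). Centring on the housekeeping list turned the medians of the Th17, Th1, Th2 and IL6 and STAT3 lists below 0.

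The other lists did not shift by camera. The interferon-stimulated list had a median of -0.06, with 1 of 50 genes up (0 adjusted over the list alone; adjusted p = 0.565), and IFNB1 itself had a log2 difference of 0.09 (adjusted p = 0.826). Medians were 0.00 for interferon signalling (2 of 11 genes rose and 4 fell), 0.04 for interferon-gamma-inducible genes (4 of 17 rose), -0.05 for class I presentation (1 of 12 rose and 2 fell), 0.06 for p53 targets (5 of 19 rose and 3 fell) and -0.12 for the TGF-beta response (2 of 24 rose and 8 fell). The values near 0 of 3 of these lists average unlike ones: at 4, 24 and 72 h the interferon-stimulated list had medians of 0.04, -0.54 and 0.06, interferon-gamma-inducible genes of 1.31, 0.41 and -0.97 and class I presentation genes of 0.14, 0.21 and -0.88. The values at 72 h are relative to an unstimulated array on which interferon-gamma-inducible genes stood apart. Markers of other blood cells had medians of -0.04 for B cells, -0.06 for monocytes, -0.11 for NK cells, 0.04 for CD8 and gamma delta T cells, -0.03 for dendritic cells and -0.01 for platelets and red cells. The NK list held GZMK, given above, and NKG7, which rose by 1.49; the dendritic list held CD1C, which rose by 0.53 but had a value of -0.19 after centring on the housekeeping list.

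The second comparison asked which genes changed with time after stimulation, across the 3 stimulated groups. Of 18260 genes 8166 varied between the 7 times (moderated F test in limma, adjusted p under 0.05). The 10 largest ranges fell into an early and a late set. FOS, NR4A2 and NR4A3 were highest at 45 min, with mean log2 intensities of 12.03, 12.54 and 12.65, and their means ranged over 5.89, 5.75 and 5.53. The cell cycle genes DTL, ESCO2, DLGAP5, CDK1 and CEP55, the histone gene H2BC14 and the membrane repair gene MYOF were highest at 24 h or 72 h, with ranges from 5.36 in CEP55 to 6.01 in DTL. For DTL the mean was 4.54 at 4 h and 10.56 at 24 h (adjusted p = 4.81e-06). The count was 9461 without the IFN-beta and Th17 arrays at 48 h, 5305 when only genes above the median level were fitted, 4995 after quantile normalization and 14660 with array weights.

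The third comparison asked how the response unfolded, setting the 3 stimulated arrays of each time against the 4 unstimulated arrays. At 45 min the largest rises were in transcription factor genes of the immediate early class: NR4A3 rose by 6.55 (SE 0.314, adjusted p = 5.2e-11), EGR3 by 5.28, EGR1 by 5.11, NR4A2 by 4.92 and FOS by 4.64. LRRN3, B3GALT2, GVINP1, NAPEPLD and GIMAP2 fell by 1.79, 1.69, 1.63, 1.54 and 1.53, and of these 5 only NAPEPLD still passed without the 24 h arrays or without the 72 h arrays. At 2 h IL2 had joined the 5 largest rises, at 4.87 (SE 0.682, adjusted p = 0.000194), and GIMAP4 and TAS2R4 the largest falls, by 1.98 and 1.94. By 4 h the largest rises were IL2 at 7.27, IL22 at 6.38, IFNG at 6.07, NR4A3 at 5.87 and the chemokine gene CCL20 at 5.63, and the largest falls were in ABCD2, TRAF3IP3, PSIP1, HPS3 and AKTIP, where ABCD2 fell by 2.46 and TRAF3IP3 by 2.35. At 10 h IL2 stood at 7.42 and IL3 at 5.42, while VSIG1 fell by 4.31, TCP11L2 by 4.06, TMEM63A by 3.87, ABCD2 by 3.64 and SORL1 by 3.51.

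At 24 h DTL rose by 5.88 (SE 0.622, adjusted p = 9.86e-07) beside IL2, CCL4, IFNG and IL21, and TCP11L2, GZMK, VSIG1, PIK3IP1 and SAMD9 fell by 5.05, 4.80, 4.60, 4.08 and 3.93. At 48 h IL21 rose by 3.94, IL2 by 3.88, SKA3 by 3.72, ESCO2 by 3.70 and DTL by 3.68, and IL7R, SESN3, PIK3IP1, TCP11L2 and GLIPR1 fell by 4.57, 4.22, 4.19, 4.19 and 4.14. Without the IFN-beta and Th17 arrays of that time, which stood apart, the values were 5.41, 5.13, 5.10, 6.17 and 5.89 for the rises and -3.14, -3.95, -4.10, -3.81 and -3.16 for the falls. At 72 h the largest rises were in DTL at 5.64, ESCO2 at 5.53, CDK1 at 5.48, DLGAP5 at 5.28 and the lipid desaturase gene SCD at 5.26, and VSIG1, GZMK, SESN3, KLRB1 and KLF3 fell by 4.71, 3.97, 3.92, 3.66 and 3.55.

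The lists differed in their course. The immediate early list had its highest median at 45 min, 1.85, with 23 of 33 genes up (adjusted p = 2.78e-75; adjusted p = 7.99e-06 with an estimated correlation). The T cell activation list had a median of 1.91 at 4 h and of 1.93 at 10 h, then with 20 of 27 genes up (adjusted p = 5.77e-19; adjusted p = 0.00516 with an estimated correlation). At 10 h the cytokine list reached 2.64, with 21 of 26 genes up (adjusted p = 2.67e-20; adjusted p = 0.00516 with an estimated correlation), and ribosome biogenesis 2.06, with 33 of 35 up (adjusted p = 9.73e-30; adjusted p = 0.0384 with an estimated correlation). DNA replication had a median of 0.20 at 10 h and 2.47 at 24 h, when 37 of 38 genes were up (adjusted p = 1.2e-32; adjusted p = 0.0432 with an estimated correlation); at 72 h it stood as high, at 2.503, with 38 of 38 up (adjusted p = 2.99e-36; adjusted p = 0.0309 with an estimated correlation). Mitosis genes reached 4.24 at 72 h, with 37 of 38 up (adjusted p = 2.41e-45; adjusted p = 0.0309 with an estimated correlation). The naive and quiescence list had a median of -0.13 at 45 min (adjusted p = 0.646) and of -1.27 at 10 h, when 13 of 23 genes were down (adjusted p = 1.49e-10; adjusted p = 0.0167 with an estimated correlation), and was lowest at 48 h, -2.04, where 2 arrays stood apart (adjusted p = 1.5e-14; adjusted p = 0.0159 with an estimated correlation).

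**Figure D2:**
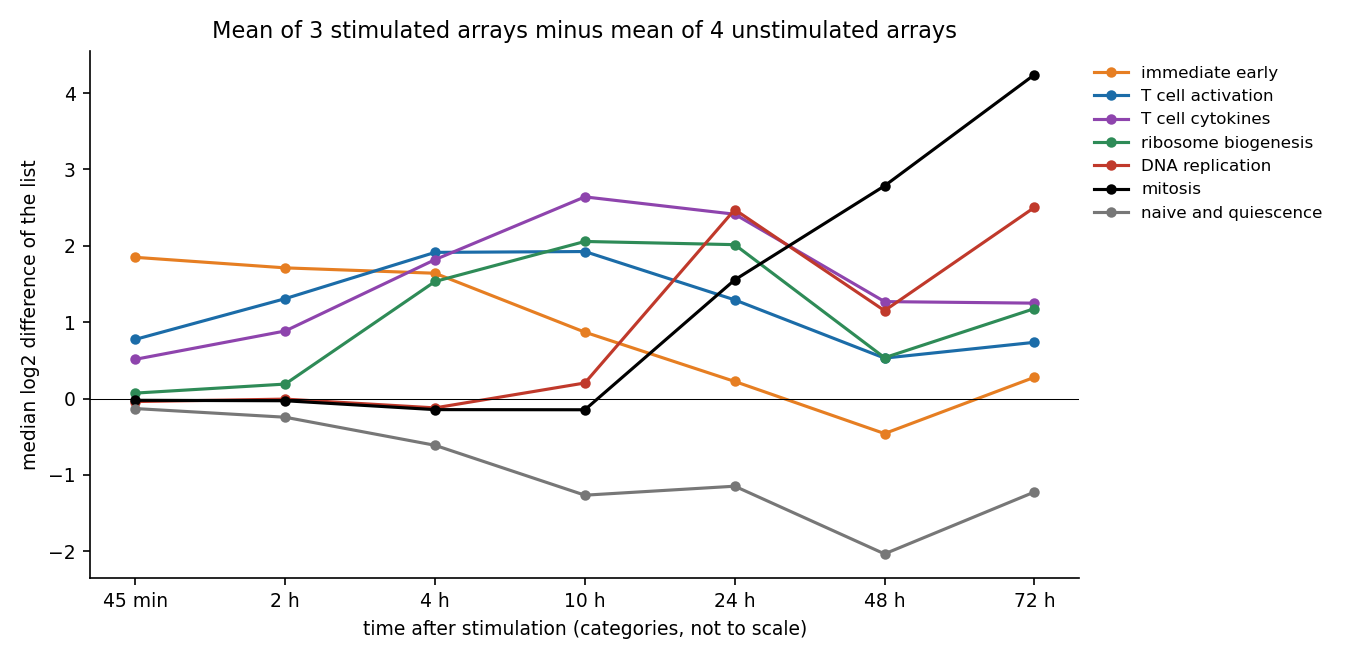
Median log2 difference of gene lists between the mean of the 3 stimulated arrays at each time and the mean of the 4 unstimulated arrays. The lists are immediate early, T cell activation, T cell cytokines, ribosome biogenesis, DNA replication, mitosis, and naive and quiescence. Times are categories and lines join the medians. The immediate early list is highest at 45 min (1.85) and the mitosis list at 72 h (4.24); at 48 h the arrays that stood apart enter 2 of the 3 stimulated values.

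Called genes numbered 363 at 45 min (221 up and 142 down), 943 at 2 h (369 and 574), 2388 at 4 h (1060 and 1328), 3508 at 10 h (1802 and 1706), 4301 at 24 h (2681 and 1620), 9287 at 48 h (5372 and 3915) and 3672 at 72 h (2155 and 1517). At 48 h, 576 genes were up and 2414 down by at least 2-fold, so most rises there were small, and with array weights 30 genes were called. The IFN-beta and Th17 arrays at 48 h weighed on all times: without them the counts were 1934, 3411, 4991, 6067, 7197, 4500 and 6522, where the 4500 at 48 h rest on 1 stimulated array, assumed to vary like the other groups. Without the 24 h arrays the counts at 45 min, 2 h, 4 h and 48 h were 120, 302, 1389 and 6016, and without the 72 h arrays those at 45 min and 2 h were 131 and 376.

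The fourth comparison asked what IFN-beta added to activation, at 7 matched times. Interferon-stimulated genes, the antiviral set that type I interferon induces, were higher in the IFN-beta arrays as a group: all 50 genes of the list had a positive mean difference, with a median of 1.12 (adjusted p = 4.72e-66; adjusted p = 0.0708 with an estimated correlation; fry adjusted p = 0.963). Of these 50 genes 0 passed the test over all genes and 9 adjusted over the list alone. The largest differences in the list were 2.15 in IFI44L (probe set 7902541; GRCh38.p14 chromosome 1, 78620448 to 78646145; SE 0.819, higher at 5 of 7 times), 1.96 in MX1 (SE 0.645, 6 of 7), 1.93 in IFI6 (SE 0.522, 6 of 7) and 1.91 in HERC6 (SE 0.499, 5 of 7). In this comparison 0 of 18260 genes were called by limma, and 210 had an unadjusted p under 0.05.

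At single times, which carry no test, the list median was 2.82 at 2 h, 2.61 at 4 h and 2.22 at 10 h, with all 50 genes higher with IFN-beta each time, and 1.03 at 24 h with 49 higher. At 48 h it was -0.18 and at 72 h -0.03. At 45 min it was -1.03, with 1 of 50 genes higher on the array labelled IFN-beta. At 10 h, IFI44L was 4.78 higher, MX1 4.49, IFI6 4.35 and USP18, a protease that curbs interferon signalling, 3.98. The chemokine gene CXCL10 was 5.01 higher at 2 h and CXCL11 3.0 at 4 h; over the 7 times their differences were 1.22 and 1.09, and those of the death ligand gene TNFSF10 and of IL10 were 0.75 and 0.64.

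**Figure D3:**
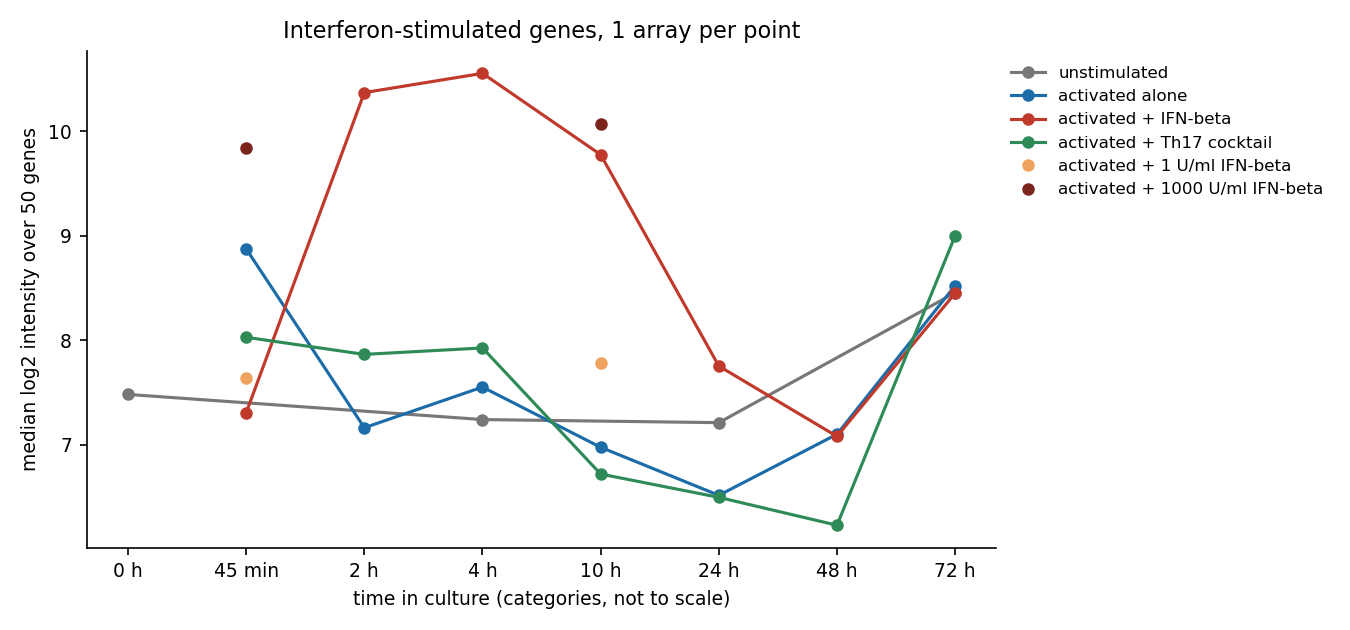
Median log2 intensity of the 50 interferon-stimulated genes on each of the 29 arrays against time in culture (categories); each point is 1 array, coloured by group, and lines join arrays of a group. At 2, 4 and 10 h the IFN-beta arrays lie above the activated arrays by median differences of 2.82, 2.61 and 2.22, while at 45 min the array labelled activated lies above the array labelled IFN-beta.

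Without all arrays at 45 min and at 48 h, a setting chosen after the data were seen, 20 genes were called and all were higher with IFN-beta; 16 belong to the interferon-stimulated list. The 45 min arrays were left out because of that same list, so this setting describes the other times and is no test of it. IFI44L was then 3.70 higher (SE 0.587, adjusted p = 0.0363), MX1 3.13, IFI44 3.09, IFIT3 3.07 and OAS1 2.87. The other 4 called genes were CD38 at 1.57 and, named after their values were seen, TRIM25 at 1.49, STAP1 at 1.00 and RBM11 at 0.72. The list median was 1.81.

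Of the 33 lists, 10 shifted with IFN-beta by camera with the preset correlation, and 0 with an estimated correlation or by fry. Upward shifts beside the interferon-stimulated list were seen in 3 more. They were interferon signalling, with a median of 0.13 (adjusted p = 0.00307; adjusted p = 0.309 with an estimated correlation), interferon-gamma-inducible genes, 0.08 (adjusted p = 0.00182; adjusted p = 0.935 with an estimated correlation), and the Th1 list, 0.16 (adjusted p = 0.000256; adjusted p = 0.0708 with an estimated correlation). Downward shifts were small. DNA replication had a median of -0.20 (adjusted p = 3.31e-06; adjusted p = 0.965 with an estimated correlation) and glycolysis of -0.18 (adjusted p = 0.00182; adjusted p = 0.965 with an estimated correlation), the housekeeping list itself had a median of -0.18 (adjusted p = 0.0248; adjusted p = 0.965 with an estimated correlation), and the medians of the mitosis, amino acid and ATF4, and T cell identity lists, from -0.16 to -0.08, turned positive after centring on the housekeeping list. Over all genes 0 members of the 10 shifted lists passed by limma, where 210 genes had an unadjusted p under 0.05. Class I presentation genes, among the targets of interferon, did not shift (adjusted p = 0.0629); from 45 min to 72 h their medians were -0.16, 0.73, 0.42, 0.37, 0.09, -0.95 and 0.06.

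The fifth comparison asked what the Th17 cocktail added to activation. At 45 min its control was the array labelled activated, whose label is in question. Some genes of Th17 cells and targets of IL6 and TGF-beta signalling had differences among the largest in their lists. Members of the IL6 and STAT3 list and of the TGF-beta response list went both ways. TGFBR3 and SMAD3, of the TGF-beta response list, had means of -0.63 and -0.42. MCL1 and HIF1A, of the IL6 and STAT3 list, had means of -0.60 and -0.50, with -4.23 and -5.10 at 48 h, on the array that stood apart. The chemokine receptor gene CCR6 was higher at all 7 times, by 0.68 (SE 0.127, adjusted p = 0.633). IL22 was higher by 0.86 (SE 0.354, 5 of 7 times), BATF by 0.68 (SE 0.292, 6 of 7), the signalling inhibitor genes SOCS3 and SOCS2 by 0.80 (SE 0.240, 6 of 7) and 0.51 (SE 0.131, 6 of 7), and the TGF-beta target PMEPA1 by 0.55 (SE 0.160, 6 of 7). GATA3, the transcription factor of Th2 cells, was lower at all 7 times, with a mean of -0.95 (SE 0.288). The means and counts of these genes include 48 h, on the array that stood apart. There CCR6 had 0.64, SOCS2 0.71, SOCS3 0.82, PMEPA1 1.40, GATA3 -1.88, IL22 -0.80 and BATF -0.53. At 45 min CCR6 had 1.31, SOCS2 0.55, SOCS3 1.54, PMEPA1 0.18, GATA3 -0.15, IL22 2.61 and BATF 2.07. For IL17F the mean difference was 0.63 and for IL17A 0.33; at 48 h, on the array that stood apart, they were -1.37 and -1.59, and at 72 h 1.54 and 0.75. By limma 0 of 18260 genes were called, and 320 had an unadjusted p under 0.05; with array weights 27 were called, among them CCR6, IL17A and IL17F.

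The Th17 list had a median of 0.09 (adjusted p = 0.0179; adjusted p = 0.62 with an estimated correlation), and 1 of its 24 genes, CCR6, passed adjusted over the list alone. Its medians at the 7 times were 0.38, 0.33, 0.26, 0.07, 0.30, -1.38 and 0.31, the sixth being 48 h. Leaving out 48 h removes the only time at which this median was below 0. The values without it therefore describe the other times and are no test of Th17 genes. Without the 48 h arrays 3 genes were called, all higher with the cocktail and named after their values were seen: the follicular helper genes CXCR5 at 1.10 (adjusted p = 0.0472) and BCL6 at 0.89 (adjusted p = 0.0431), and DSE at 0.61 (adjusted p = 0.0358). With the 45 min arrays left out too, 10 genes were called and all were higher. By limma IL17F was 1.23 higher (SE 0.169, adjusted p = 0.00987) and IL17A 0.80 (SE 0.114, adjusted p = 0.0103), each at 5 of 5 times. The times left out were the only ones at which these genes were lower, so this is no test of them. IL17F had -0.37 at 45 min and -1.37 at 48 h, and IL17A -0.10 and -1.59. The rest, named after their values were seen, were CXCR5, BCL6, DSE, FLVCR2, ITGA2, OTUD1, FURIN and ADAM19, by 0.60 to 0.88. The Th17 list then had a median of 0.35 with 2 genes called and 11 adjusted over the list alone (adjusted p = 4e-14; adjusted p = 0.00781 with an estimated correlation).

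**Figure D4:**
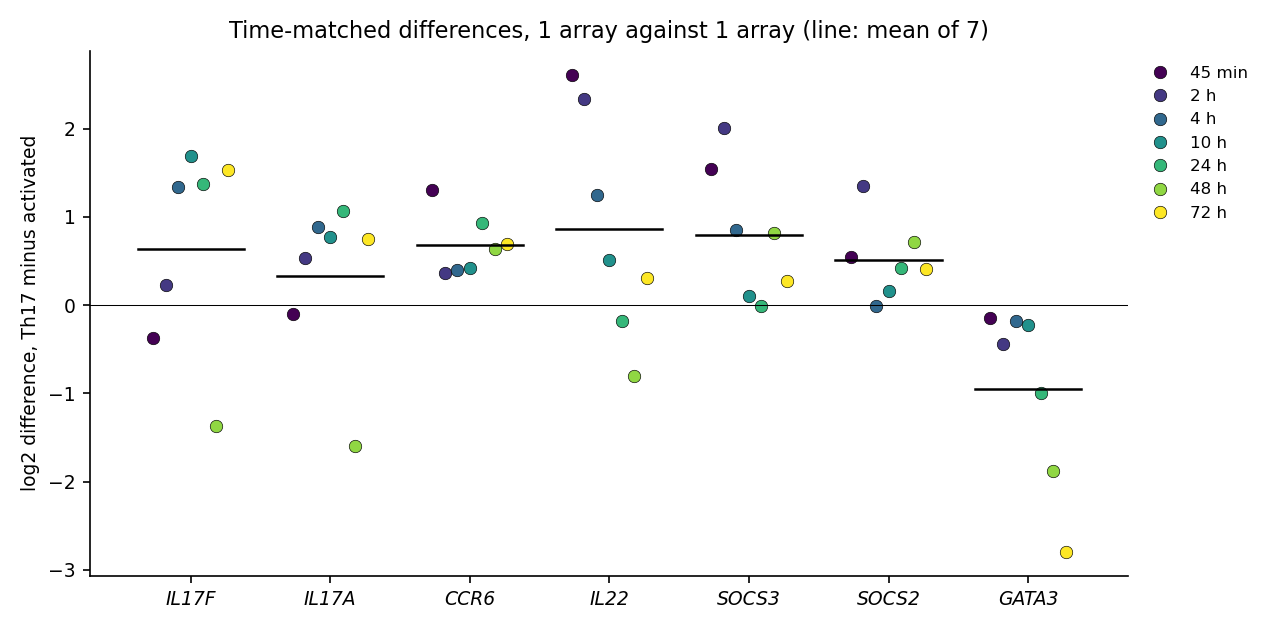
Log2 differences between the Th17 and the activated array of the same time for 7 genes, 1 point per time with the mean of 7 as a line. CCR6 lies above 0 and GATA3 below 0 at all 7 times. IL17A and IL17F are lowest at 48 h (-1.59 and -1.37). The Th17 array at 48 h, which stood apart, gives 1 of the 7 points of each gene.

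Of the 33 lists 18 shifted by camera with the preset correlation, 3 up and 15 down, and 0 with an estimated correlation or by fry. The upward ones were the Th17 list, the TGF-beta response with a median of 0.10 (adjusted p = 0.0186; adjusted p = 0.526 with an estimated correlation) and the IL6 and STAT3 list with 0.16 (adjusted p = 0.00704; adjusted p = 0.541 with an estimated correlation). In the IL6 and STAT3 list 2 genes passed adjusted over the list alone, SOCS2 and SOCS3, and 0 over all genes. The largest downward median was that of mitosis genes, -0.46 (adjusted p = 1.08e-13; adjusted p = 0.526 with an estimated correlation). It was -0.04 without the 45 min and 48 h arrays (adjusted p = 0.555), so this shift rests on those times, and most of the other downward medians turned positive under cyclic loess, array weights or centring on the housekeeping list.

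The sixth comparison set the cocktails against each other. Interferon-stimulated genes were higher with IFN-beta than with the Th17 cocktail, with a list median of 1.09 and 49 of 50 genes positive (adjusted p = 1.86e-55; adjusted p = 0.201 with an estimated correlation), and 21 passed adjusted over the list alone. IFI44L was 2.73 higher (SE 0.819) and IFI44 2.42 (SE 0.705), each at 5 of 7 times. On the Th17 side, SOCS2 had a difference of -0.63 (SE 0.131) and CCR6 of -0.65 (SE 0.127), both at 7 of 7 times and both with adjusted p = 0.917 by limma. These include 48 h, where both arrays stood apart and the values were -0.93 for SOCS2 and -0.84 for CCR6. IL17F had a difference of -0.71 (SE 0.291, 6 of 7 times). IL10 was 0.95 higher with IFN-beta (SE 0.307, 5 of 7 times). By limma 0 genes were called and 369 had an unadjusted p under 0.05; with array weights 111 were called, 21 higher with IFN-beta and 90 with the Th17 cocktail. Of the lists, 15 shifted by camera with the preset correlation and 0 with an estimated correlation or by fry.

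Without the 45 min and 48 h arrays 25 genes were called, 11 higher with IFN-beta and 14 higher with the Th17 cocktail. Where interferon-stimulated and Th17 genes are concerned, this is again a description of the other times and no test. On the IFN-beta side were 5 genes of the interferon-stimulated list, with IFI44L at 3.53, CD38 at 1.86 (SE 0.247, adjusted p = 0.00699) and, named after their values were seen, SLFN12L at 1.07 and the death ligand gene FASLG at 0.58. On the Th17 side were IL17F at -1.07 (SE 0.169, adjusted p = 0.0274) and, also named after their values were seen, FLVCR2 at -0.85, BCL6 at -0.78, CXCR5 at -0.71 and FURIN at -0.62. The Th17 list had a median of -0.43, with 1 gene called and 12 adjusted over the list alone (adjusted p = 1.04e-07; adjusted p = 0.064 with an estimated correlation).

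Whether each effect differed between early (45 min, 2 h and 4 h) and late times (10 to 72 h) was tested as an interaction. For IFN-beta the interferon-stimulated list had a late minus early median of -0.50 (adjusted p = 0.000116; adjusted p = 0.624 with an estimated correlation), and for the Th17 cocktail the Th17 list had one of -0.30 (adjusted p = 0.000687; adjusted p = 0.36 with an estimated correlation). By limma 0 genes were called for either, with 190 and 3267 at an unadjusted p under 0.05; with array weights 0 and 2904 were called. Of the lists 19 shifted for IFN-beta and 29 for the cocktail by camera with the preset correlation, 0 for either with an estimated correlation, and 0 and 1 by fry. Without the 48 h arrays 1 list shifted for IFN-beta and 22 for the cocktail; the interferon-stimulated median was -0.28 (adjusted p = 0.163) and the Th17 list median 0.017 (adjusted p = 0.161, with the test pointing down). Without 45 min and 48 h the interferon-stimulated median was -1.39 (by camera with an estimated correlation, adjusted p = 0.242, where all times gave 0.624). In that setting 6 genes were called for IFN-beta, all with a lower effect at late times. They were GBP4 and, named after their values were seen, AZI2, CNP, PRKD2, TRIM14 and TRIM38. For the cocktail 6 were called, also all with a lower effect at late times and named after their values were seen: TNFRSF10D, RPL22L1, VAV1 and 3 small RNAs.

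The last comparison asked how the response scaled with dose, at 1000 U/ml against 1 U/ml of IFN-beta. Interferon-stimulated genes were higher at 1000 U/ml: all 50 were positive, with a median of 1.71 (adjusted p = 2.63e-100; adjusted p = 0.00995 with an estimated correlation; fry adjusted p = 0.702). The median was 1.57 at 45 min and 1.74 at 10 h. Each of the 10 named genes of the list was higher at 1000 U/ml at both times, from 1.27 at 45 min and 1.73 at 10 h upward. IFIT1, an RNA sensor of viral transcripts, was 4.81 higher at 45 min and 4.22 at 10 h, from levels of 5.86 and 5.54 at 1 U/ml; whether these lie above background was not tested. Interferon-gamma-inducible genes had a median of 0.79 (by camera, adjusted p = 9.66e-23, and adjusted p = 0.00836 with an estimated correlation). Their median was 0.88 at 45 min and 0.49 at 10 h. CXCL10 had a difference of 4.50 (SE 1.25), which was 6.52 at 45 min and 2.49 at 10 h. Medians were 0.33 for interferon signalling (adjusted p = 1.14e-06; adjusted p = 0.0144 with an estimated correlation), 0.24 for the IL6 and STAT3 list (adjusted p = 4.39e-09; adjusted p = 0.0286 with an estimated correlation) and 0.27 for the Th1 list (adjusted p = 8.4e-06; adjusted p = 0.00995 with an estimated correlation). By limma 0 genes were called and 127 had an unadjusted p under 0.05. Adjusted over the list alone, 1 gene passed among the interferon-gamma-inducible genes (CXCL10) and 1 in the IL6 and STAT3 list (OSM at 1.19), and 0 in the interferon-stimulated, interferon signalling and Th1 lists. Of the lists 9 shifted with the preset correlation, 5 with an estimated one and 0 by fry.

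Against activated cells of the same time the doses differed at 10 h: the median of the interferon-stimulated list was 0.69 at 1 U/ml and 2.54 at 1000 U/ml. At 45 min the values were -0.79 and 0.72, measured against the array labelled activated 45 min. On the array labelled activated 45 min IFIT1 had a log2 intensity of 9.49, against 5.20 on the array labelled IFN-beta, 5.86 at 1 U/ml, 10.67 at 1000 U/ml and 5.55 in unstimulated cells at 0 h. With 1 array per dose and time, the values at single times carry no test.

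**Figure D5:**
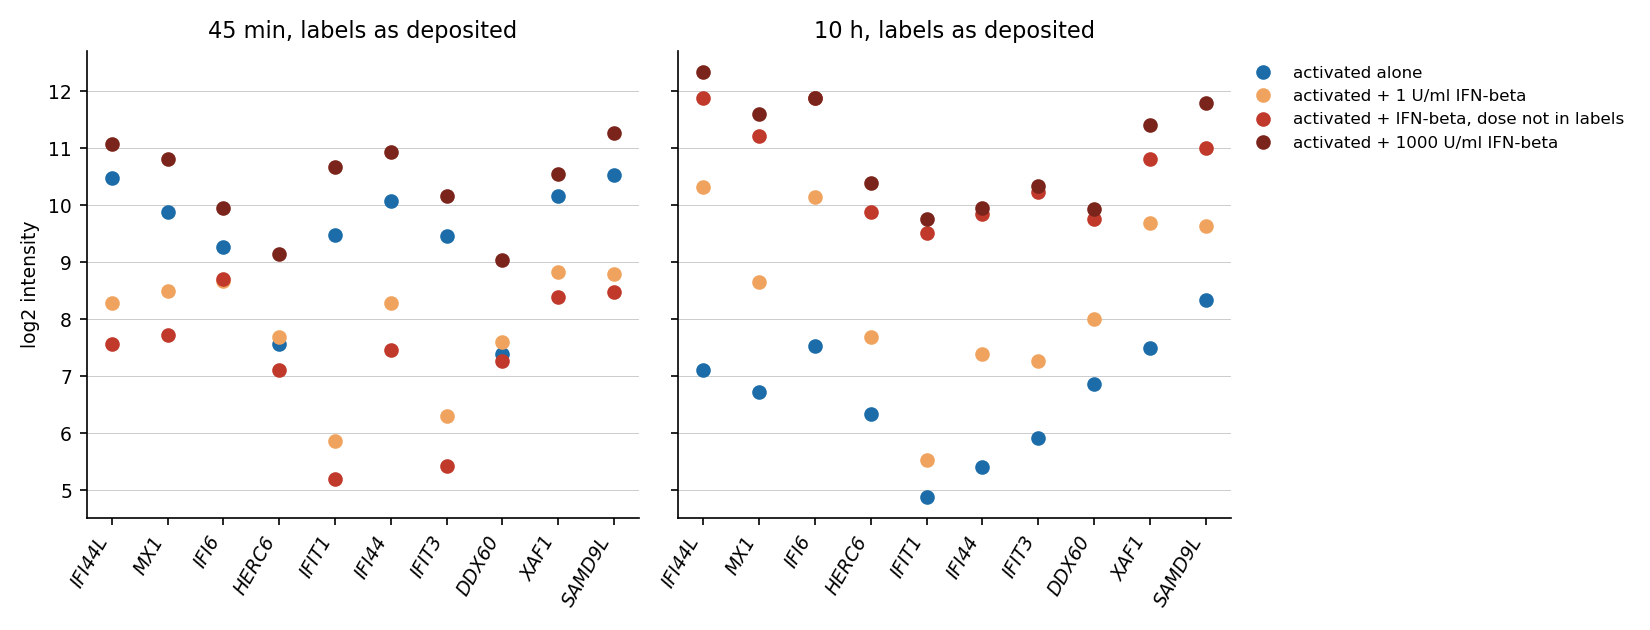
Log2 intensity of 10 interferon-stimulated genes at 45 min and at 10 h on the arrays labelled activated, 1 U/ml, IFN-beta (dose not in the labels) and 1000 U/ml; each point is 1 array. All 10 genes are higher at 1000 U/ml than at 1 U/ml at both times, by 1.27 or more at 45 min and by 1.73 or more at 10 h.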

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

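Several tests in this part were chosen after the result was seen. They were those of exchanged labels within the interferon-stimulated list, of IFN-beta not yet acting or delayed and of interferon in the activated culture. The same holds for those of scale alone, of a lasting Th17 effect and of activated cells in the unstimulated culture. The others were fixed before the values they measure were seen, except the test of a whole-array difference at 45 min. That test measures the list median that had raised the question. Among 25 groups of values 5 held an outlier, where chance flags about 1 in 20 groups. The median correlation with the other arrays was 0.8657 for IFN-beta at 48 h (others 0.9151 to 0.9524) and 0.4574 for Th17 at 48 h (others 0.9109 to 0.956). The median log2 level of interferon-gamma-inducible genes was 9.299 on the unstimulated 72 h array (others 6.607 to 6.701). The Th17 list stood apart at 48 h, with a median of -1.383 against activated cells (others 0.0694 to 0.3778) and of 0.7921 for IFN-beta minus Th17 (others -0.4244 to -0.1109), 2 values that share the Th17 array. By the interaction test 2 effects differed between late and early times: the interferon-stimulated list under IFN-beta, -0.5032 (adjusted p = 0.000116; adjusted p = 0.624 with an estimated correlation), and the Th17 list under the cocktail, -0.3049 (adjusted p = 0.000687; adjusted p = 0.36 with an estimated correlation). Without 48 h neither passed by camera, with medians of -0.28 and 0.017 (adjusted p = 0.163 and 0.161). Without 45 min and 48 h the interferon-stimulated median was -1.39. For it only camera with an estimated correlation is given (adjusted p = 0.242, to be set beside the 0.624 with all times).

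At 45 min interferon-stimulated genes were lower on the array labelled IFN-beta than on the array labelled activated, by a list median of -1.035, where random lists gave 0.04 to 0.29, which argues against a difference of the whole arrays. A delay of IFN-beta alone would leave the 2 arrays alike, so by itself it would not give this pattern, with 49 of 50 genes lower. That value is the pattern itself and no separate test. The array labelled activated lay 0.876 above unstimulated cells, with 45 of 50 genes above (SD 1.16 over the genes, which is not the precision of the median). With 1 such array this by itself decides nothing. An exchange of the 2 labels could give this but stays open: the array labelled activated lay 0.789 above the 1 U/ml array, a value close to the pattern itself, and outside the interferon lists, across 18172 genes, a test fixed beforehand came out against it (correlation -0.0137, 0.231 in the control at 2 h). That test is diluted: it runs on genes outside the interferon lists, whose differences between the 2 arrays (SD 0.41) were wider than those between the doses (SD 0.229). Interferon in the activated culture alone stays open too. The array labelled IFN-beta lay below the 1 U/ml array (-0.295), with 43 of 50 genes lower, which goes against it by the rule written for this test. The spread over the genes (SD 0.315) does not measure the precision of this median. The difference is 1 array against 1 and the dose of the array labelled IFN-beta is not in the labels, so no conclusion is drawn. The labels were used as given.

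The Th17 array at 48 h had a mean Spearman correlation of 0.419 with the Th17 arrays at 24 and 72 h, which a change of scale alone would leave high (lowest among the other 28 arrays 0.8465). A lasting effect of the cocktail is argued against by the correlation of Th17 with activated arrays at 24 and 72 h, 0.986 at its lower. For the 500 genes brightest on the other arrays 98.8% lay below the Th17 arrays at 24 and 72 h (median -3.54), but the narrow range of values on this array fixes that outcome, and the dimmest 500 had a median of 0.95. Loss of signal from abundant transcripts therefore stays open, with no test for it.

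On the unstimulated 72 h array 9 of 17 interferon-gamma-inducible genes lay above both the 24 h unstimulated array and all 3 stimulated arrays at 72 h by over 0.5, more than a mix of these could give. The monocyte marker list did not rise as a whole, with a median of 0.0996 over 24 h, where a larger share of monocytes was predicted to give over 0.5. Of its 18 markers 1, LYZ, was over 0.5 higher, at 3.19. Whether the other markers lie above background was not tested, so the list cannot decide on a larger share of monocytes. What raised these genes stays open, as no other biological explanation was tested.

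Other splits of the arrays were counted, the real one included. For activated against unstimulated 1 of 63 splits, the real one, gave as many genes (3382, highest other 1). The same held for the time course (1 of 100, 8166 genes, highest other 1977). It held too, with 1 of 35 splits each, at 2 h (943 against 570), 4 h (2388 against 1310) and 10 h (3508 against 1716). At 24 h the counts were 4301 against 2021, at 48 h 9287 against 6389 and at 72 h 3672 against 1479. The splits exchange single cultures of unlike treatment or time, with no correction over the comparisons, so these counts do not exclude chance. At 45 min 2 of 35 splits gave as many (363, highest other 449), so chance cannot be excluded there either. For IFN-beta, Th17 and IFN-beta against Th17, each with 0 genes by limma (210, 320 and 369 at an unadjusted p under 0.05), and for the interactions, with 0 genes too (190 and 3267), the count says nothing about chance, since every split gives at least 0 (64 of 64 and 35 of 35; highest other 0, and 8 for the IFN-beta interaction). The interferon-stimulated median of 1.124 was reached in 10 of 64 splits (highest other 1.487) and the Th17 list median of 0.0912 in 49 of 64 (highest other 0.7396), so chance cannot be excluded for either.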

How the results depend on the processing

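Quantile normalization and the 2 settings that leave out arrays at 45 min or 48 h were chosen after the data were seen; all others were fixed before the data were examined. Of the summary values outside the leave-one-out settings 228 stayed the same, 85 moved and 2 were weaker; the cause was not tested. Genes changed by activation (3382) numbered 13711 after centring on the housekeeping list, 1309 with no replicate block in place of paired times, and 4 with only the 2 groups compared; the lists shifted (21) numbered 0 with an estimated correlation. The time course (8166 genes) gave 5305 for genes above the median level, 14660 with array weights and 4995 after quantile normalization.

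With an estimated correlation 0 lists shifted for IFN-beta, Th17, IFN-beta against Th17 and both interactions, 5 for the doses and 36 in place of 123 over all single times; with fry 0 shifted for IFN-beta, Th17, IFN-beta against Th17, the IFN-beta interaction and the doses, 1 for the Th17 interaction, and 6, 9, 13, 19, 22, 11 and 19 at the single times in order. For Th17 against activated, 10 lists shifted among genes above the median level, 9 with cyclic loess, 10 with array weights and 11 without 45 min and 48 h, where 18 shifted in the main setting. For IFN-beta against Th17 (15) the first 3 settings each gave 9. For the IFN-beta interaction (19) they gave 1, 2 and 7, quantile normalization 2, the setting without the 2 arrays at 48 h 1 and without 45 min and 48 h 8. For the Th17 interaction (29) the values were 5 above the median level, 10 with cyclic loess and 18 without both times; for the doses (9), 14 without both times.

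Gene counts of 0 became 27 for Th17, 111 for IFN-beta against Th17 and 2904 for the Th17 interaction with array weights. Without the 2 arrays at 48 h they were 3, 1 and 6, and without both times 10, 25 and 6, with 20 for IFN-beta, 6 for its interaction and 1 for the doses (SLFN12L). In that last setting the doses are 1 array against 1, at 10 h, assumed to vary like the other groups. The Th17 list median was 0.0601 after quantile normalization and 0.0912 with no replicate block, where it no longer passed.

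At single times, in the order 45 min, 2, 4, 10, 24, 48 and 72 h, array weights gave 5257, 5290, 5855, 6829, 9493, 30 and 7874 genes, the setting without the 2 arrays at 48 h 1934, 3411, 4991, 6067, 7197, 4500 and 6522, and the 0 h array alone as baseline 125, 194, 826, 1538, 1963, 1819 and 1484. Without both times 2, 4, 10, 24 and 72 h gave 4064, 5463, 6499, 7877 and 6998. The activated array alone gave 142 at 45 min, 182 at 2 h, 1073 at 4 h and 3349 at 48 h. Cyclic loess gave 689 and 1518 at 45 min and 2 h; centring on the housekeeping list gave 128, 334 and, at 48 h, 2563; genes above the median level gave 4176 at 48 h.

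Leaving out 1 time in turn gave these ranges. Activated against unstimulated: 314 to 5342 genes, 21 to 22 lists. IFN-beta: 0 to 0 genes, 8 to 13 lists, interferon-stimulated median 0.78 to 1.57. Th17: 0 to 3 genes, 14 to 19 lists, Th17 median 0.0419 to 0.3394. IFN-beta against Th17: 0 to 1 genes, 13 to 17 lists. Interactions: 0 to 0 genes and 1 to 23 lists for IFN-beta, 0 to 6 genes and 22 to 29 lists for Th17. Doses: 0 to 0 genes, 9 to 13 lists, median 1.57 to 1.74. Time course: 5869 to 9464. Single times in order: 120 to 1934, 302 to 3411, 1389 to 4991, 2537 to 6067, 3463 to 7197, 6016 to 9476 and 2673 to 6522, and 97 to 111 lists over the 6 times left in each setting.

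Over all settings of the named genes 2178 values stayed the same, 183 were weaker, 18 stronger and 2 reversed. The 2 were IFNB1 (-0.63) and CD1C (-0.19), in activated against unstimulated after centring on the housekeeping list.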

Other observations

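Unstimulated cells also differed between times in culture. Interferon-gamma-inducible genes, such as chemokines and guanylate-binding proteins, had medians of 0.03 at 4 h, -0.09 at 24 h and 1.69 at 72 h relative to 0 h. The class I presentation list, which serves display of antigens on the cell surface, had medians of -0.13, -0.07 and 0.94, and the interferon-stimulated list of -0.19, -0.19 and 0.80. These are single arrays and carry no test.

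Marker lists of other cells had no such median: at 4, 24 and 72 h the monocyte list had -0.19, -0.32 and -0.18, the NK list -0.43, -0.30 and -0.10 and the dendritic list -0.15, -0.08 and -0.02. Single myeloid markers were higher on the 72 h array, with log2 levels of 9.03 against 5.84 at 24 h and 7.49 at 0 h for LYZ, and of 10.57 against 6.83 and 6.29 for the chemokine gene CCL22, which were picked after their values were seen. The mitosis list was 0.31 above its 0 h level at 72 h and the naive and quiescence list had a median of -0.30. Because the 72 h array is 1 of 4 unstimulated arrays in the comparisons at single times, these shifts enter every difference from unstimulated cells.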
